A study of Homo sapiens with 8 samples.

How the data were processed

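RNA sequencing was done on SC1, a human cell line of diffuse large B-cell lymphoma (DLBCL). Per the labels' protocols, cells received DMSO, alisertib at 100 nM, SGC-CBP30 at 10 µM or both drugs together for 24 h, with 2 replicates in each of the 4 groups (8 libraries). Alisertib inhibits Aurora kinase A (AURKA), and SGC-CBP30 binds the bromodomains of the histone acetyltransferases CREBBP and EP300. Total RNA was taken with Trizol, and the libraries followed standard Illumina procedures, per the labels' protocols. The kit and its strandedness are not given in the sources used here, so reads of a gene and of an antisense partner may be mixed. Groups and replicate numbers were taken from the labels. Nothing says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

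The deposited table gives 1 score per gene and library for 39272 gene symbols. These scores are whole numbers on a linear scale, and their sum over genes lay between 999193 and 999528 in every library. They were therefore read as shares of a common total (per-million values) that the authors had rounded to whole numbers. Which formula was used, and whether it divided by gene length, is not given in the sources used here. Per the submitters' processing notes, fastp, Trim Galore, HISAT2, featureCounts and the GRCh38 build were used, with no versions, roles or settings. Read totals cannot be had from such values, so the depth is unknown and no counting interval or limit is given. Rounding removes differences among low genes, and pairs of replicates at the same whole number then show no spread. A gene listed at 0 may be a failed estimate, so only the listed values are given for such genes.

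Values were taken as log2(value + 1), and every fold change below is on that scale, which understates changes of low genes. Genes with a value of at least 1 in at least 2 libraries were kept, which left 14204. Limma 3.58.1 in R 4.3.3 fitted the 4 group means to all 8 libraries with a trended prior variance, which leaves 4 residual degrees of freedom. Contrasts were alisertib, SGC-CBP30 and the combination against DMSO, the combination against each single drug, and the interaction, which asks whether the effect of the combination departs from the sum of both drug effects on the log2 scale. Adjusted p-values are Benjamini-Hochberg values within a contrast, and 0.05 was the threshold. With 2 against 2 samples an exact permutation test cannot go below p = 0.333, so none was used. This model, the gene lists, the fixed genes and the rule for naming genes were chosen before the data were examined.

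DMSO replicate 2 stood apart from the other 7 libraries, and a second fit was added after this had been seen. The first version left that library out and kept the same filter. It passed 458 genes for alisertib, 1150 for SGC-CBP30, 1692 for the combination, 2704 for the combination against alisertib, 285 against SGC-CBP30 and 460 for the interaction. On simulated data for alisertib against DMSO with DMSO replicate 2 deviating as observed (13902 genes, 200 of them changed), that version made 214 false calls among 342. Raising the minimum to 5 gave 7 false calls among 138 (10064 genes). The version with the minimum of 5 is called the 7-library fit here. It tested 10205 genes with 3 residual degrees of freedom and was chosen after the data and the counts of the first version had been seen. Its comparisons against DMSO rest on DMSO replicate 1 alone, which is assumed to vary like the other groups. Fold changes of the combination against alisertib or SGC-CBP30 use no DMSO library in either fit, but their test shares its estimate of spread with DMSO.

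Both fits were tested on such simulated data, drawn anew for each minimum value, with 200 genes changed by known amounts. All 200 lay at or above the median level, so recovery of lower genes was not measured. Every gene was drawn independently, and the simulated DMSO replicate 1 carried no shift shared by many genes. False calls that such a shift would make in the 7-library fit were therefore not measured. For log2 changes of 0.5, 1, 2 and 3, the 8-library fit recovered 0%, 0%, 20% and 40% of the changed genes, with 21 false calls among 51, of which 20 had a mean of at most 2. The 7-library fit recovered 16%, 60%, 86% and 100%. In a separate simulation that raised only the list of G2/M and mitosis genes by 0.5 on the log2 scale, its camera adjusted p was 2.04e-44 and 0 of 22 other lists passed. That simulation drew every gene independently and left out the deviation of DMSO replicate 2. It therefore does not show how often camera passes unchanged lists of correlated genes in these data.

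24 gene lists were fixed: MYC targets, E2F and S-phase genes, G2/M and mitosis genes, p53 targets, histone genes, MHC class II, MHC class I, germinal-centre B-cell genes, plasma-cell genes, interferon response, NF-kB targets, apoptosis regulators, ATF4 and unfolded-protein stress genes, sterol biosynthesis, glycolysis and hypoxia, ribosomal proteins, oxidative phosphorylation, the mitochondrial genome, immediate-early and heat-shock genes, BET bromodomain response genes, and acetyltransferase, bromodomain and Aurora genes, with markers of T and NK cells, myeloid cells, and stromal and epithelial cells. Limma's camera compared each list with the other tested genes at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. The same test with an estimated correlation, and limma's fry, which asks whether a list's members move one way on balance, were run beside it. With an estimated correlation, camera rests on the residual degrees of freedom (4, or 3 in the 7-library fit). It then has little power, and a lost call need not reflect correlation. With all 8 libraries the MHC class II estimate was 0.029, near the preset value, yet camera's adjusted p for SGC-CBP30 rose from 1.98e-11 to 0.0622. Estimates in that fit ran from 0.018 for BET bromodomain genes to 0.853 for the mitochondrial genome. They were 0.591 for G2/M and mitosis genes, 0.591 for histone genes and 0.494 for germinal-centre B-cell genes. In the 7-library fit these lists had 0.355, 0.499 and 0.0297. Where the estimate lay far above 0.01, camera's p at the preset value may be too small, and correlation may also end a call. Lists with fewer than 3 tested members were left out. Members were counted as passing over all genes tested and adjusted over the list alone.

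Named genes followed a rule. For each drug against DMSO, the 10 genes with the largest rise and the 10 with the largest fall were taken among those past the threshold. Both treated libraries had to lie beyond both DMSO libraries, and the mean over libraries had to reach the median of the tested genes. With fewer than 3 such genes, the 5 genes of smallest p in each direction were given as values. The other contrasts used 5 genes per direction. 16 fixed genes were followed in every contrast, and up to 4 members of smallest p per list. Some genes that this rule covers are not reported here. Coordinates come from GENCODE v29 on GRCh38, matched by symbol for 74 of 77 named genes. Genes with near-identical copies, among them the HLA class II genes, NCF1, NAPSB, IGLL1 and the histone genes, may share reads and are uncertain.

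The effects of other pseudocounts, filters, scalings, prior variances and thresholds, of a fit to the compared groups alone, of the replicate number as a block, and of leaving out each library are given in the closing section. Unchanged groups that share the DMSO libraries were simulated 100 times as a background for comparing both drugs. A count model needs whole reads, which could not be recovered from rounded values, so limma was used for every test.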

Results

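Expression was measured by RNA sequencing in SC1 lymphoma cells after 24 h of DMSO, alisertib (100 nM), SGC-CBP30 (10 µM) or both drugs (the combination), with 2 libraries per group. The series concerns AURKA as a target in DLBCL with deficient CREBBP, and the expression of MYC. Values are whole numbers scaled to nearly the same sum in every library, and 14204 of 39272 genes reached 1 in at least 2 libraries. The depth of the libraries is unknown.

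DMSO replicate 2 differed from the other 7 libraries. Pearson's r across tested genes, which are not independent replicates, was 0.851 to 0.905 between it and the others and 0.969 to 0.993 among those others. RN7SL1, a small cytoplasmic RNA, had a value of 62605 there against 5783 to 9947 elsewhere, and SNORD3A, a small nucleolar RNA, had 16890 against 50 to 96. Histone list genes made up 16.5% of the summed values in DMSO replicate 2 and 2.31% to 4.002% in the other libraries. Genes of the mitochondrial genome made up 0.598% there and 1.82% to 2.65% elsewhere. The SD across genes of the log2 difference between replicates was 1.16 for DMSO, 0.278 for alisertib, 0.359 for SGC-CBP30 and 0.287 for the combination. Both fits are therefore given, with all 8 libraries and with the 7 libraries other than DMSO replicate 2.

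**Figure D1:**
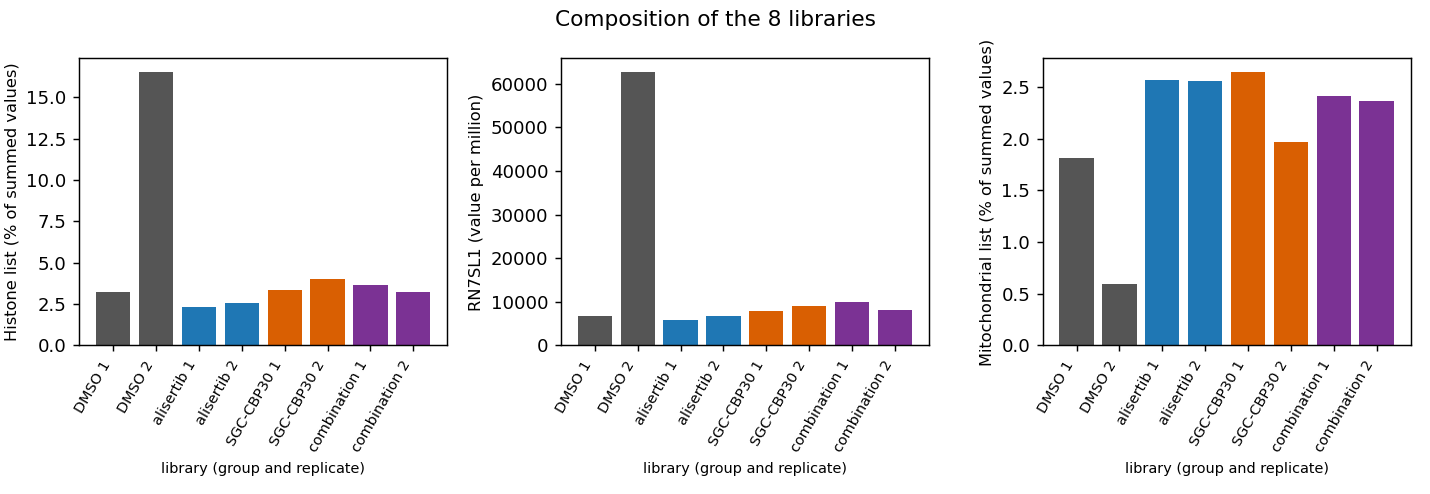
Bars show, for each of the 8 libraries, the percent of summed values in the histone list, the RN7SL1 value and the percent of summed values in the mitochondrial list. DMSO replicate 2 stands at 16.5%, 62605 and 0.598%, outside the range of the other 7 libraries in each panel.

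The genes named by the series title were followed first. MYC, a transcription factor gene that drives growth (chromosome 8, 127735434 to 127741434), had values of 331 and 95 in DMSO, 351 and 329 with alisertib, 278 and 263 with SGC-CBP30, and 220 and 244 with the combination. In the 7-library fit MYC fell with the combination against DMSO (log2 fold change -0.51 ± 0.09 SE, limma adjusted p = 0.0281) and against alisertib (-0.55 ± 0.07, adjusted p = 0.00862). Its changes with alisertib (0.04 ± 0.09, adjusted p = 0.775) and with SGC-CBP30 (-0.29 ± 0.09, adjusted p = 0.134) did not pass limma's threshold. With all 8 libraries neither MYC call held, with 0.38 ± 0.58 against DMSO (limma adjusted p = 0.617), the opposite sign, and -0.55 ± 0.58 against alisertib (adjusted p = 0.974). CREBBP, the target of SGC-CBP30 (chromosome 16, 3725054 to 3880726), had 288 and 60 in DMSO, 321 and 334 with alisertib, 314 and 302 with SGC-CBP30, and 369 and 385 with the combination. CREBBP rose with the combination in the 7-library fit (0.39 ± 0.07, limma adjusted p = 0.0271). With all 8 libraries its estimate was 1.51 ± 0.72 and did not pass (adjusted p = 0.297). AURKA, the target of alisertib (chromosome 20, 56369389 to 56392337), had 69 and 18 in DMSO, 111 and 106 with alisertib, 65 and 54 with SGC-CBP30, and 93 and 92 with the combination. No AURKA comparison passed, the smallest limma adjusted p being 0.0845 for the combination against DMSO in the 7-library fit (0.42 ± 0.12).

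**Figure D2:**
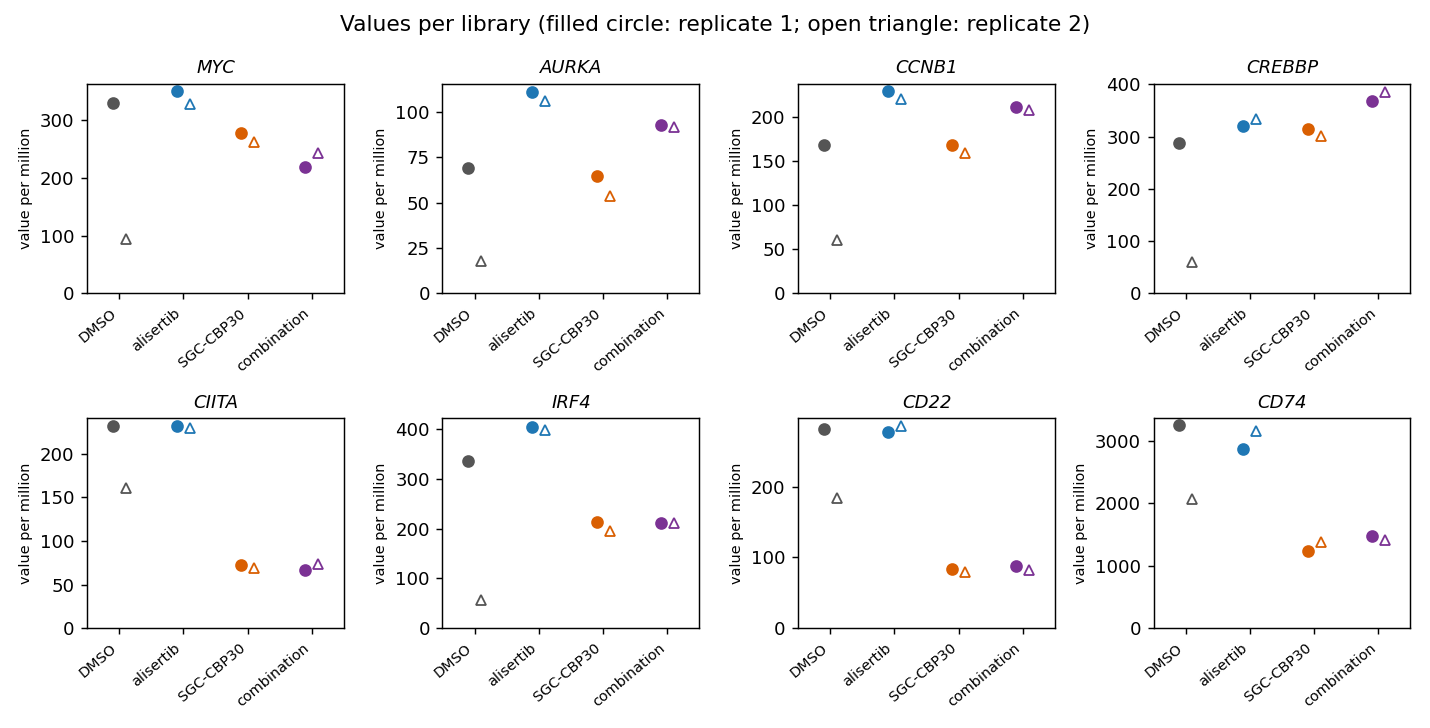
Points give the value of 8 genes in each library, with filled circles for replicate 1 and open triangles for replicate 2. CIITA, CD22 and CD74 lie lower in all 4 libraries with SGC-CBP30 than in the other 4, and the MYC value of DMSO replicate 2 (95) lies below that of every other library.

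Alisertib against DMSO asked what inhibition of AURKA alone changed. CCNB1, the cyclin of entry into mitosis, had 168 and 61 in DMSO against 229 and 220 with alisertib (7-library fit 0.42 ± 0.07, limma adjusted p = 0.251). CDCA8, a subunit of the chromosomal passenger complex, had 190 and 76 against 240 and 245 (0.35 ± 0.06, adjusted p = 0.251). MAZ, a zinc-finger transcription factor gene, fell from 352 and 350 to 228 and 214 and passed with all 8 libraries (-0.67 ± 0.09, limma adjusted p = 0.0475). Its 7-library estimate was alike (-0.67 ± 0.09) but did not pass the threshold.

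The G2/M and mitosis list was higher after alisertib in limma's camera test, with adjusted p = 0.0222 in the 8-library fit (adjusted p = 0.981 with an estimated correlation) and 3.77e-05 in the 7-library fit (adjusted p = 0.69 with an estimated correlation). Its median log2 fold change was 1.62 and 0.52, beside a median over all tested genes of 0.58 and 0.21. 0 of its 40 and 0 of its 39 tested members passed over all genes, while 0 and 11 rose when adjusted over the list alone. Besides CCNB1, CDCA8 and AURKA, the members of smallest p included KIF2C (0.41 ± 0.08 in the 7-library fit, adjusted p = 0.251). The histone list was lower (camera adjusted p = 3.42e-13 and 2.3e-10, medians -1.56 and -0.38, adjusted p = 0.814 and 0.496 with an estimated correlation), with 0 members past the threshold, also when adjusted over the list alone. H3C14, a histone H3 gene outside that list, had 433 and 1251 in DMSO against 79 and 54. Its 7-library estimate was -2.71 ± 0.33 with alisertib, -2.32 ± 0.33 with SGC-CBP30 and -1.94 ± 0.33 with the combination. Its lower value against DMSO was thus not particular to alisertib. The higher histone share of DMSO replicate 2 bears on the 8-library median of the list. Mitochondrial genome genes, whose share also set DMSO replicate 2 apart, had larger medians after alisertib than the G2/M list (2.14 and 0.67, camera adjusted p = 0.0708 and 0.00776, adjusted p = 0.981 and 0.69 with an estimated correlation).

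Limma passed 219 genes for alisertib with all 8 libraries (194 higher, 25 lower), of which 214 had a mean of at most 2, and 2030 had an unadjusted p under 0.05. In the 7-library fit 0 of 10205 passed, with 2022 at an unadjusted p under 0.05. By the naming rule the remaining genes of smallest p in the 8-library fit were NEAT1 (1.12 ± 0.22), GABPB2, CLK1, GARS1-DT and DLEU2 above 0, with LRFN4 (-0.68 ± 0.11), RNF187 and MIR3648-1 below 0, with adjusted p between 0.101 and 0.247. With DMSO replicate 1 left out, 9898 genes passed, and with SGC-CBP30 replicate 1 or replicate 2 left out, 376 did. Centring each library on its median moved the median of all genes from 0.58 to -0.38, and 0 genes passed then.

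SGC-CBP30 against DMSO asked what the bromodomain inhibitor alone changed. KCNN4, TCL1A, CD27 and CIITA fell, and H1-10 rose. KCNN4, a calcium-activated potassium channel gene (chromosome 19, 43766533 to 43781261), fell from 44 and 48 to 5 and 5 (8-library fit -2.97 ± 0.14, limma adjusted p = 0.000413). TCL1A, an AKT coactivator of germinal-centre B cells, fell from 405 and 404 to 136 and 149 (limma adjusted p = 0.00152). CD27, a receptor of memory B cells and plasma cells, fell from 40 and 32 to 5 and 6 (-2.50 ± 0.18, adjusted p = 0.003). CIITA, the master regulator of MHC class II (chromosome 16, 10866222 to 10943021), fell from 232 and 161 to 72 and 69 (-1.44 ± 0.19, adjusted p = 0.0348). H1-10, a linker histone gene, rose from 45 and 42 to 194 and 168 (2.03 ± 0.23, adjusted p = 0.0192). All 5 also passed in the 7-library fit, where limma's adjusted p lay between 0.00457 and 0.0172.

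The germinal-centre B-cell list was lower with SGC-CBP30 (camera adjusted p = 2.03e-12 and 1.06e-22 in the 8- and 7-library fits, medians -0.47 and -0.84, adjusted p = 0.4 and 0.0587 with an estimated correlation). Of its 33 tested members, 4 fell over all genes with all 8 libraries (6 adjusted over the list alone) and 21 in the 7-library fit (27 adjusted over the list alone), and 0 rose. CD22, an inhibitory coreceptor of the B-cell receptor, fell from 281 and 184 to 83 and 79 (-1.48 ± 0.21, limma adjusted p = 0.0449). CD40 also fell (-0.78 ± 0.11, adjusted p = 0.0414). IRF8 (51 and 13 to 9 and 9) and CD79A (403 and 221 to 137 and 153) fell in the 7-library fit (-2.38 ± 0.12 and -1.47 ± 0.09, adjusted p = 0.00457 and 0.00468).

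The MHC class II list was lower as well (camera adjusted p = 1.98e-11 and 1.72e-07, means -0.72 and -1.01, adjusted p = 0.0622 and 0.0587 with an estimated correlation). 4 of 9 tested members fell with all 8 libraries and 5 of 8 in the 7-library fit (6 and 6 adjusted over the list alone). HLA-DQB1 fell from 116 and 114 to 53 and 50 (-1.14 ± 0.09, limma adjusted p = 0.00603), and HLA-DRB1 from 231 and 296 to 85 and 93 (-1.55 ± 0.15, adjusted p = 0.0109). HLA-DRA, which also passed with all 8 libraries, was at 1 in every library without SGC-CBP30 and listed at 0 in the others. Its call thus rests on a step of 1 in rounded values. In the list, 6 of 15 members were listed at 0 in all 8 libraries. So were 105 of 127 coding genes from HLA-F to HLA-DPB1, the stretch of chromosome 6 that holds HLA-DRA. CD74, the invariant chain, had 3255 and 2060 against 1233 and 1372.

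Plasma-cell genes (camera adjusted p = 5.65e-06 and 1.72e-07, adjusted p = 0.355 and 0.0587 with an estimated correlation) and NF-kB targets (2.79e-06 and 1.27e-06, adjusted p = 0.324 and 0.0587 with an estimated correlation) were lower with SGC-CBP30. 3 and 5 of 13 plasma-cell members fell (3 and 8 adjusted over the list alone), among them MZB1 from 241 and 280 to 65 and 76 (-1.87 ± 0.19, limma adjusted p = 0.0126) and TNFRSF17 from 5 and 4 to 1 and 1 (-1.45 ± 0.13, adjusted p = 0.0081). IRF4, a B-cell and plasma-cell transcription factor gene, had 335 and 57 in DMSO against 214 and 196, and fell in the 7-library fit (-0.71 ± 0.07, adjusted p = 0.0103), while the 8-library estimate was 0.56 ± 0.81 (adjusted p = 0.626). 1 and 5 of 14 NF-kB targets fell (4 and 9 adjusted over the list alone), among them RELB from 189 and 207 to 107 and 120 (-0.80 ± 0.10, adjusted p = 0.0326).

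MYC targets were lower than other genes with SGC-CBP30 in camera (adjusted p = 0.000729 and 1.72e-07, adjusted p = 0.61 and 0.263 with an estimated correlation), although their median was 0.25 with all 8 libraries and -0.32 in the 7-library fit. Centring turned the 8-library median to -0.46 and quantile normalization gave 0.04. LDHA, a glycolytic enzyme gene, was the 1 of 35 members that fell in the 7-library fit (-0.52 ± 0.09, limma adjusted p = 0.0358), and 0 fell when adjusted over the list alone. Histone genes were lower with all 8 libraries (1.31e-07, median -0.96, adjusted p = 0.538 with an estimated correlation) and higher in the 7-library fit (0.0357, median 0.22, adjusted p = 0.825 with an estimated correlation), and H1-10 was the 1 member that rose in each, also when adjusted over the list alone.

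Limma passed 327 genes for SGC-CBP30 with all 8 libraries (203 higher, 124 lower), 194 of them with a mean of at most 2, and 688 in the 7-library fit (327 higher, 361 lower). 115 genes passed in both, in the same direction. Further genes named by the rule in the 8-library fit were MOV10, PLCD3, PINK1, TRO, TMEM175, SKOR1, FLOT2, TUBA1A and PPP1R26 among those that rose (1.08 to 1.68) and LCK (-2.75 ± 0.22, adjusted p = 0.00574), ITGAL, IGLL1, NAPSB, CYTH4, SPNS3 and HLA-DRB5 among those that fell. The share of higher calls was 62.1% with all 8 libraries, 5.71% of 35 calls after centring and 5.77% of 52 after quantile normalization. Leaving out DMSO replicate 1 gave 9610 genes, and leaving out DMSO replicate 2 gave 1150.

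The combination against DMSO asked what both drugs together changed. KCNN4 and CIITA fell here too, and JUN, JUND and H1-10 rose. JUN, a subunit of the AP-1 transcription factor, rose from 4 and 6 to 46 and 50 (8-library fit 3.05 ± 0.23, limma adjusted p = 0.00289). JUND, its relative (chromosome 19, 18279760 to 18281622), rose from 223 and 176 to 652 and 821 (1.88 ± 0.17, adjusted p = 0.00604), and H1-10 rose to 223 and 346 from 45 and 42 (2.65 ± 0.23, adjusted p = 0.00556). KCNN4 fell to 6 and 5 from 44 and 48 (-2.86 ± 0.14, adjusted p = 0.000372), and CIITA to 67 and 74 from 232 and 161 (-1.44 ± 0.19, adjusted p = 0.0259). DUSP2, a phosphatase gene of the immediate-early list, fell (-1.31 ± 0.15, adjusted p = 0.0171).

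Of the 33 germinal-centre B-cell genes, 5 fell with all 8 libraries and 21 in the 7-library fit (6 and 26 adjusted over the list alone), with camera adjusted p = 5.61e-11 and 1.76e-20 (adjusted p = 0.396 and 0.0728 with an estimated correlation). TCL1A (-1.56 ± 0.09, limma adjusted p = 0.000967), BLK (-1.12 ± 0.16, adjusted p = 0.0368) and CD22 (-1.41 ± 0.21, adjusted p = 0.0389) were among them. MHC class II genes were lower (camera adjusted p = 9.51e-11 and 1.86e-07, adjusted p = 0.0701 and 0.0728 with an estimated correlation), with 4 of 9 and 5 of 8 members that fell (6 and 6 adjusted over the list alone), HLA-DQB1 by -1.04 ± 0.09 (adjusted p = 0.00672). Plasma-cell genes (4.65e-06 and 1.87e-07, adjusted p = 0.315 and 0.0728 with an estimated correlation) counted 3 and 6 of 13 that fell (3 and 7 adjusted over the list alone), and NF-kB targets (8.72e-05 and 2.18e-05, adjusted p = 0.315 and 0.088 with an estimated correlation) 1 and 5 of 14 (4 and 9 adjusted over the list alone, where 1 NF-kB target rose in each fit and 1 plasma-cell gene in the 7-library fit).

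MYC targets were lower with the combination in camera (adjusted p = 1.07e-07 and 1.85e-13, adjusted p = 0.396 and 0.121 with an estimated correlation). Their median was 0.18 with all 8 libraries, where centring gave -0.57 and quantile normalization -0.08, and -0.42 in the 7-library fit. 0 of 36 members passed with all 8 libraries and 9 of 35 fell in the 7-library fit (0 and 20 adjusted over the list alone). These included NME1, a nucleoside diphosphate kinase gene (107 and 90 to 72 and 71, 7-library -0.58 ± 0.08, limma adjusted p = 0.015), LDHA (-0.63 ± 0.09, adjusted p = 0.0168), UTP20 (-0.82 ± 0.13, adjusted p = 0.0205) and MRTO4 (-0.59 ± 0.10, adjusted p = 0.0245). G2/M and mitosis genes were higher (camera adjusted p = 0.00696 and 0.00124, medians 1.26 and 0.30, adjusted p = 0.701 and 0.604 with an estimated correlation), with 1 of 40 and 9 of 39 that rose (1 and 16 adjusted over the list alone). PSRC1, a spindle protein gene, rose in both fits (1.16 ± 0.17 and 1.00 ± 0.14, limma adjusted p = 0.035 and 0.0165), and CDCA8 rose in the 7-library fit (0.49 ± 0.06, adjusted p = 0.0119), as did CCNB1 (0.32 ± 0.07, adjusted p = 0.0444).

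Among the other fixed genes, HEXIM1, an inhibitor of transcription elongation that responds to bromodomain inhibitors, rose in the 7-library fit (11 and 3 to 24 and 28, 1.17 ± 0.23, limma adjusted p = 0.0345), and IRF4 fell (-0.66 ± 0.07, adjusted p = 0.0108). Neither passed with all 8 libraries. Against DMSO, the Aurora kinase gene AURKB, the acetyltransferase gene EP300, the lymphoma genes BCL6, BCL2 and MCL1, the cell-cycle inhibitor gene CDKN1A and PRDM1, a regulator of plasma cells, did not pass with any treatment in either fit. Limma passed 499 genes for the combination with all 8 libraries (364 higher, 135 lower), 266 of them with a mean of at most 2, and 1273 in the 7-library fit (817 higher, 456 lower), with 202 in both and in the same direction. The rule also named SORT1 (9 and 2 to 59 and 71, adjusted p = 0.0498), MOV10, SGSH, ATP6V0A1, TOM1L2, PINK1, DYRK1B and TMEM175 among those that rose, and LCK, IGLL1, CD27, NAPSB, CYTH4, MZB1, ITGAL, NCF1 and SPNS3 among those that fell. The share of higher calls was 72.9% with all 8 libraries (11.1% of 27 calls after centring, 13.8% of 58 after quantile normalization) and 64.2% in the 7-library fit (49.2% and 52.4%). Without DMSO replicate 1 the count was 9998, and without DMSO replicate 2 it was 1692.

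The combination against alisertib asked what SGC-CBP30 added to alisertib, and its fold changes do not use DMSO. KCNN4 and CIITA fell, and H1-10 and JUND rose. H1-10 had 49 and 51 with alisertib and 223 and 346 with the combination (8-library fit 2.45 ± 0.23, limma adjusted p = 0.00979), JUND 252 and 243 against 652 and 821 (1.56 ± 0.17, adjusted p = 0.0159). KCNN4 fell from 40 and 40 to 6 and 5 (-2.66 ± 0.14, adjusted p = 0.00074), and CIITA from 232 and 229 to 67 and 74 (-1.70 ± 0.19, adjusted p = 0.0195). CD180, a B-cell surface receptor gene of the BET bromodomain list, had 5 and 4 with alisertib and was listed at 0 with the combination (adjusted p = 0.0372).

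Against alisertib, the germinal-centre B-cell list was lower (camera adjusted p = 1.01e-12 and 8e-13, median -1.01 in each fit, adjusted p = 0.583 and 0.169 with an estimated correlation), with 3 and 28 of 33 members that fell (5 and 31 adjusted over the list alone). MHC class II genes (8.75e-08 and 0.00042, adjusted p = 0.13 and 0.169 with an estimated correlation) counted 4 of 9 and 7 of 8 that fell (6 and 7 adjusted over the list alone). Plasma-cell genes (4.06e-05 and 0.000588, adjusted p = 0.583 and 0.169 with an estimated correlation) counted 3 and 10 of 13 that fell (3 and 10 adjusted over the list alone), and 1 rose in the 7-library fit. JCHAIN, the joining chain of immunoglobulins, fell from 161 and 164 to 27 and 22 in the 7-library fit (-2.69 ± 0.12, limma adjusted p = 0.0015), but its adjusted p was 0.413 with all 8 libraries. NF-kB targets (camera adjusted p = 0.0001 and 0.00126, adjusted p = 0.583 and 0.169 with an estimated correlation) counted 0 and 9 of 14 that fell (1 and 10 adjusted over the list alone). MYC targets were lower (0.0001 and 6.77e-06, median -0.45 in each fit, adjusted p = 0.694 and 0.459 with an estimated correlation), with 0 of 36 and 22 of 35 that fell (0 and 24 adjusted over the list alone). Histone genes were higher in the 7-library fit (2.9e-06, median 0.54, adjusted p = 0.464 with an estimated correlation), where 13 of 23 rose (19 adjusted over the list alone). RN7SL1, which with histone genes set DMSO replicate 2 apart, was at 5783 and 6724 with alisertib and at 9947 and 8021 with the combination.

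Limma passed 319 genes against alisertib with all 8 libraries (160 higher, 159 lower) and 3214 in the 7-library fit (1611 higher, 1603 lower), and 123 passed in both in the same direction. Of the 319, 185 had a mean of at most 2. The rule also named MOV10, PINK1 and ORAI3 among those that rose, and IGLL1, ITGAL, LCK and CD27 among those that fell. 2 of 16 tested fixed genes passed with all 8 libraries (CIITA and HLA-DRA), and 10 of 15 in the 7-library fit, among them BCL6 (-0.53 ± 0.13, adjusted p = 0.035), MCL1 (-0.43 ± 0.12, adjusted p = 0.0497), PRDM1 (-1.81 ± 0.32, adjusted p = 0.0147, values of at most 6), IRF4 (-0.92 ± 0.06, adjusted p = 0.00211) and AURKB (0.20 ± 0.05, adjusted p = 0.0359). With all 8 libraries the adjusted p of BCL6 was 1, of MCL1 0.996, of PRDM1 0.254, of IRF4 0.914 and of AURKB 0.596. The share of higher calls was 50.2% with all 8 libraries and 15.4% of 26 calls after quantile normalization. With either DMSO library left out, 2718 (replicate 1) and 2704 (replicate 2) genes passed.

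The combination against SGC-CBP30 asked what alisertib added. JUN rose from 13 and 10 to 46 and 50 and passed with all 8 libraries (1.98 ± 0.23, limma adjusted p = 0.0476). Its 7-library estimate was the same (1.98 ± 0.16) but did not pass the threshold. G2/M and mitosis genes were higher (camera adjusted p = 0.000701 and 4.05e-12, median 0.35 in each fit, adjusted p = 0.912 and 0.415 with an estimated correlation), with 0 of 40 and 0 of 39 past the threshold (0 and 16 rose when adjusted over the list alone). AURKA (65 and 54 to 93 and 92, 0.63 ± 0.10 in the 7-library fit) and CCNB1 (168 and 159 to 211 and 208, 0.36 ± 0.06) each had limma adjusted p = 0.531 there. MYC targets were lower (camera adjusted p = 9.19e-07 and 7.62e-13, median -0.14 in each fit, adjusted p = 0.775 and 0.292 with an estimated correlation), with 0 members past the threshold, also when adjusted over the list alone. MYC itself had -0.22 ± 0.07 in the 7-library fit (limma adjusted p = 0.589).

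Limma passed 104 genes against SGC-CBP30 with all 8 libraries (87 higher, 17 lower), of which 100 had a mean of at most 2, and 0 of 10205 in the 7-library fit, where 797 had an unadjusted p under 0.05. None met the naming rule. Counts without 1 library were 284 and 285 (DMSO replicates 1 and 2), 276 and 171 (SGC-CBP30 replicates 1 and 2) and 177 (combination replicate 1). The interaction passed 221 genes with all 8 libraries (66 higher, 155 lower), 220 of them with a mean of at most 2, and 0 in the 7-library fit, with 368 at an unadjusted p under 0.05. No fixed gene passed for the interaction, the smallest limma adjusted p being 0.527 and 0.717 in both fits. Without DMSO replicate 1 it passed 8700 genes, without DMSO replicate 2 460, and without SGC-CBP30 replicate 2 382.

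Limma's fry, which asks about a list by itself, passed 0 lists in either fit for alisertib, the combination against SGC-CBP30 and the interaction, with adjusted p = 0.359 and 0.312 for G2/M and mitosis genes after alisertib. It passed 2 lists for SGC-CBP30, 2 for the combination and 3 for the combination against alisertib with all 8 libraries, and 6, 8 and 10 in the 7-library fit. MHC class II genes passed fry in these 3 comparisons in both fits, for SGC-CBP30 with adjusted p = 0.00241 and 0.000635. Germinal-centre B-cell genes passed it only in the 7-library fit, for SGC-CBP30 with adjusted p = 0.00103.

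**Figure D3:**
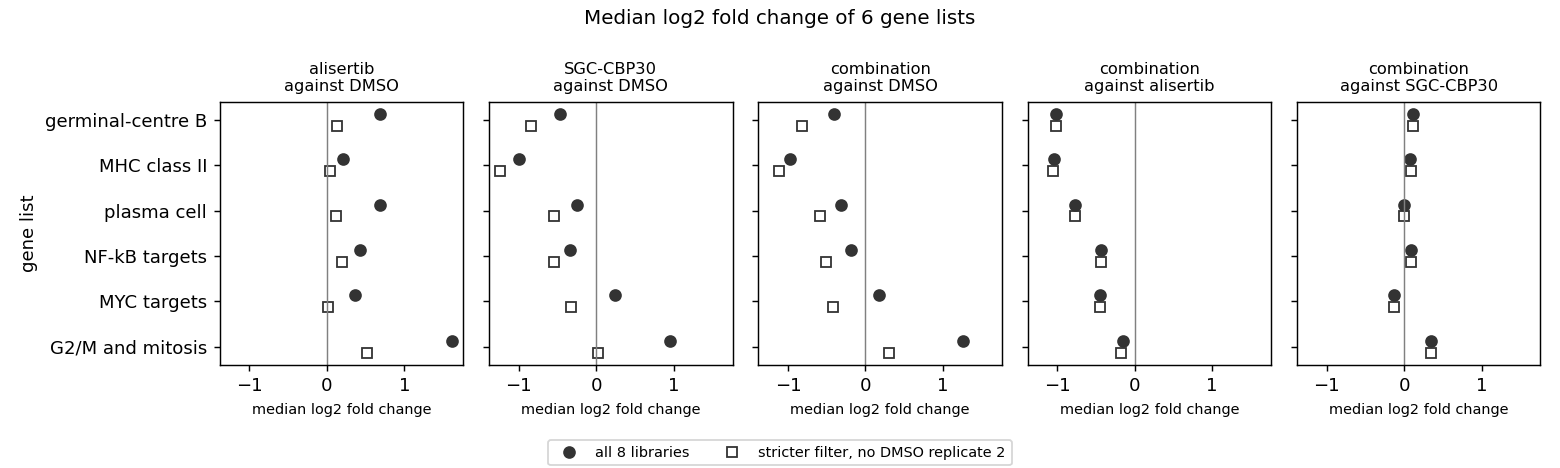
Each panel gives the median log2 fold change of 6 gene lists for 1 comparison, with filled circles for the fit to all 8 libraries and open squares for the 7-library fit. The germinal-centre B-cell median lies at -1.01 in both fits against alisertib, and the MYC target median changes sign between fits for SGC-CBP30 (0.25 and -0.32) and the combination (0.18 and -0.42) against DMSO.

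Alisertib and SGC-CBP30 were also compared with each other through their fold changes against DMSO. Across genes, Pearson's r was 0.760 and Spearman's rho 0.770 with all 8 libraries, and r was 0.933 for simulated unchanged groups that share the DMSO libraries. The covariance was 0.364 against 0.336 simulated, and 80.6% of genes had the same sign against 83.4% simulated. Simulated fold changes were centred on 0, while the observed medians over all genes were 0.58 for alisertib and 0.50 for SGC-CBP30. Such a shift raises the observed same-sign share by itself, so observed and simulated shares are not on a like footing. In the 7-library fit r was 0.0573 (rho -0.0324, simulated r 0.669), the covariance 0.00713 against 0.0261 simulated, and the same-sign share 46.3% against 73.2% simulated. In both fits r and the same-sign share lay below those of simulated unchanged groups, while the 8-library covariance lay above. With all 8 libraries 92 genes passed as higher with both drugs, against 2.77 for independent lists, and 15 as lower, against 0.218. The shared DMSO libraries raise this overlap, so it does not show a common response. The 2 DMSO libraries of the 8-library fit were not split between both drugs, since 1 library would be left on each side. Without DMSO replicate 2 and with the 8-library filter r was 0.241.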

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

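The weighing of transcript length and of a few abundant features for DMSO replicate 2 was chosen after the deviation of that library had been seen, and the 7-library fit was likewise chosen after the data were seen.

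A test of the interaction asks whether the effect of alisertib differs with and without SGC-CBP30. It passed 221 genes with all 8 libraries, 220 of them with a mean of at most 2, and 0 in the 7-library fit (limma, 368 at an unadjusted p under 0.05). Histone genes had a median interaction of 1.45 (camera adjusted p = 1.35e-10), and it was 0.30 in the 7-library fit. The mitochondrial genome list had a median of -2.04 (camera adjusted p = 0.0338), and -0.63 in the 7-library fit. DMSO enters the interaction, and DMSO replicate 2 stood apart in both histone genes (16.5% of summed values) and mitochondrial genes (0.598%). The 8-library medians of these lists therefore cannot be told apart from the deviation of that library. All 7-library medians rest on DMSO replicate 1 alone. ATF4 and unfolded-protein stress genes had a median of -0.157, with a mean of the same sign, while camera placed them higher than other genes (adjusted p = 0.0185), whose median was -0.50, and the 7-library median was 0.22. Immediate-early and heat-shock genes had a median of -0.264 and were placed higher too (adjusted p = 0.0491), with 0.18 in the 7-library fit. All 4 lists passed camera in the same direction in the 7-library fit too (adjusted p = 7.9e-08 for histone genes, 0.000294 for the mitochondrial genome, 2.54e-05 for stress genes and 0.000704 for immediate-early genes). With an estimated correlation all 4 had adjusted p = 0.978 with all 8 libraries and 0.721, 0.721, 0.293 and 0.635 in that order in the 7-library fit. In both fits 0 members passed in any of them, also when adjusted over the list alone. Centring turned the medians of the stress list to 0.75 and of the immediate-early list to 0.65, and quantile normalization turned them to 0.34 and 0.09.

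DMSO replicate 2 stood apart from the other 7 libraries. RNA of another cell type, or a swapped outside sample, would bring its own abundant transcripts, but 0 coding genes reached 20 there while listed at 0 in the other 7 libraries. A few features that take a large share of the values would leave the remaining genes in proportion. Without histone genes and short noncoding RNAs, the SD of the DMSO replicate difference over 6211 genes was still 1.18, or 4.66 times the largest SD among the other groups. Loss of long transcripts relative to short ones may contribute, since Spearman's rho between the replicate difference and exonic length was -0.291 over 9383 coding genes, just short of the bound of -0.3 set for that explanation, and SGC-CBP30 had -0.233 between its replicates. No biological explanation was tested, as both DMSO libraries belong to 1 group.

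G2/M and mitosis genes were higher in both comparisons that add alisertib. Scaling of the libraries and an RNA composition like that of DMSO replicate 2 were weighed against an effect of alisertib. Among 10000 random lists matched on the DMSO replicate difference and level, the list's median (0.52 against DMSO and 0.35 against SGC-CBP30) lay at percentile 100 in both comparisons, above limits, exceeded by 1 in 40 random lists, of 0.33 and 0.10. After quantile normalization, with lists matched on level alone, it again lay at percentile 100 (0.35 and 0.30, limits 0.11 and 0.04). The list thus lay above unrelated genes of like level or DMSO replicate difference. Members of this list are correlated, which random lists do not carry, so a technical shift shared by these genes is not excluded. An effect of alisertib on mitotic transcripts or on the share of mitotic cells stays a hypothesis. In both comparisons 0 members passed over all genes, and estimated correlations ended the list calls.

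Germinal-centre B-cell genes were lower in both comparisons that add SGC-CBP30. For RNA composition along the axis of DMSO replicate 2, the list's medians (-0.84 against DMSO and -1.01 against alisertib) lay at percentile 0 of 10000 matched lists, below limits of -0.11 and -0.27. For scaling of the libraries, tested by quantile normalization, with lists matched on level alone, they lay at percentile 0 as well (-0.80 and -0.997, limits -0.09 and -0.16). The list thus lay below unrelated genes of like level or DMSO replicate difference. Random lists do not carry the correlation among members of a list, so a technical shift shared by these genes is not excluded. Lower expression of these genes under SGC-CBP30 stays a hypothesis, found and tested on the same libraries. The list calls themselves ended with an estimated correlation (adjusted p = 0.0587 against DMSO and 0.169 against alisertib in the 7-library fit).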

How the results depend on the processing

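The 7-library fit, its centred version and the centred fit without DMSO replicate 2 were chosen only after the data had been seen, and all other settings here were planned. Single genes were followed under centring, both other pseudocounts, the replicate block, each left-out library, the 7-library fit and centring without DMSO replicate 2. In all of these KCNN4 and CD27 kept their direction and call with SGC-CBP30 and with the combination against DMSO. With the stricter filter and all 8 libraries 0 genes passed in any comparison, which ended the calls of these 2 genes and of all others. Of 293 gene results, 93 passed with all 8 libraries and 0 of those turned direction in these settings, while 55 that had not passed turned in at least 1. Of the 93, 84 no longer passed after centring, 40 with the replicate block, 2 in the 7-library fit (which did not test 11 others), 11 after centring without DMSO replicate 2, 2 with a pseudocount of 0.1 and 4 with a pseudocount of 5. Leaving out 1 treated library ended 35 to 50 of these calls, and leaving out a DMSO library ended 0. Where a group keeps 1 library, that library is assumed to vary like the other groups. The 293 gene results held genes named in the 8-library fit, fixed genes and some list members. Those list members were kept because they had passed in the 8- or 7-library fit. How many results that had not passed with all 8 libraries do so in the 7-library fit is therefore partly fixed by that choice. Of the gene results that had not passed, 121 passed in the 7-library fit, 9 of them in the opposite direction, and 93 after centring without DMSO replicate 2, 8 of them in the opposite direction. The cause was not tested for any value that turned below. Unknown depth and rounding to whole values limit what can be said of genes near 1. The planned count-model test on recovered reads was not run, since reads cannot be recovered from rounded values. Replicate differences correlated between groups with r from -0.0411 to 0.320, and not all pairs exceeded 0.1, so equal replicate numbers were not taken as pairs.

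Counts of genes past the threshold moved as follows, from 219 for alisertib, 327 for SGC-CBP30, 499 for the combination, 319 for the combination against alisertib, 104 against SGC-CBP30 and 221 for the interaction. With the stricter filter of 5 and all 8 libraries, 0 passed in all 6. Centring gave 0, 35, 27, 0, 0 and 0, and quantile normalization 0, 52, 58, 26, 0 and 0. The 7-library fit gave 0, 688, 1273, 3214, 0 and 0, and centring without DMSO replicate 2 gave 2, 839, 1366, 4359, 1 and 1. Centring the 7-library fit itself gave 13, 1029, 1609, 4229, 6 and 4. A fit to the compared groups only gave 527 for alisertib, 3732 against alisertib and 414 against SGC-CBP30. The replicate block gave 199 for SGC-CBP30, 312 for the combination and 206 against alisertib, and moved no other count by over 1.5 times. A threshold of 0.01 gave 192, 278 and 193 for these 3. Leaving out 1 library gave 263 to 9898 for alisertib, 296 to 9610 for SGC-CBP30, 334 to 9998 for the combination, 251 to 2718 against alisertib, 120 to 285 against SGC-CBP30 and 250 to 8700 for the interaction. Lists past the threshold numbered 4, 9, 13, 6, 8 and 4 in the same order, and 0 in all 6 with an estimated correlation. For alisertib the 7-library fit passed 7 lists and centring without DMSO replicate 2 passed 8. Leaving out 1 library gave 1 to 6, 7 to 10, 9 to 14, 5 to 7, 4 to 8 and 1 to 5 lists. The correlation of both drugs' fold changes was 0.760, ran from 0.241 to 0.927 when 1 library was left out, and was 0.0573 in the 7-library fit.

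Centring with all 8 libraries turned the estimates with alisertib of GABPB2 (-0.0368), GARS1-DT (-0.0533), MYC (-0.0301) and CIITA (-0.71). With SGC-CBP30 the same setting turned IRF4 (-0.14), PSAT1 (-0.28), MYC (-0.10), AURKB (-0.68), CCNB1 (-0.0176) and MCL1 (-0.0170). With the combination the same setting turned LDHA (-0.0312), CD83 (-0.75), PSAT1 (-0.40), MYC (-0.37), AURKB (-0.68), IRF4 (-0.15), PTTG1 (-0.15), PIF1 (-0.12) and MXD3 (-0.17). For the combination against alisertib the same setting turned EP300 (0.13) and CCNB1 (0.11). For the combination against SGC-CBP30 the same setting turned IRF4 (-0.0064). For the interaction the same setting turned CCNB1 (0.13), CIITA (0.66), HEXIM1 (0.0935) and PRDM1 (0.26). The 7-library fit turned the estimates with alisertib of CIITA (-0.0093). With SGC-CBP30 the same setting turned LDHA (-0.52), IRF4 (-0.71), PSAT1 (-0.65), MYC (-0.29), EP300 (-0.0210), AURKA (-0.22), CCNB1 (-0.0395), BCL6 (-0.23) and MCL1 (-0.23). With the combination the same setting turned LDHA (-0.63), UTP20 (-0.82), CD83 (-0.64), PSAT1 (-0.71), MYC (-0.51), BCL6 (-0.16), BCL2 (-0.0636), MCL1 (-0.13) and IRF4 (-0.66). For the interaction the same setting turned CREBBP (0.11), CIITA (0.0079) and PRDM1 (0.0146). With a pseudocount of 0.1 the PRDM1 interaction became 0.21, and with a pseudocount of 5 the estimate of CD83 with the combination became -0.0108.

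Centring without DMSO replicate 2 turned the estimates with alisertib of MYC (-0.26), CREBBP (-0.12), EP300 (-0.0532), CIITA (-0.31), MCL1 (-0.0064) and IRF4 (-0.0415). With SGC-CBP30 the same setting turned LDHA (-0.56), IRF4 (-0.75), PSAT1 (-0.69), MYC (-0.33), EP300 (-0.0615), AURKA (-0.26), CCNB1 (-0.0800), BCL6 (-0.27) and MCL1 (-0.27). With the combination the same setting turned LDHA (-0.72), UTP20 (-0.92), CD83 (-0.73), PSAT1 (-0.81), MYC (-0.61), BCL6 (-0.25), BCL2 (-0.16), MCL1 (-0.23) and IRF4 (-0.75). For the combination against alisertib the same setting turned EP300 (0.13) and CCNB1 (0.11). For the combination against SGC-CBP30 the same setting turned IRF4 (-0.0064). For the interaction the same setting turned CREBBP (0.36), EP300 (0.19), AURKA (0.24), CCNB1 (0.19), CIITA (0.26), HEXIM1 (0.22), MCL1 (0.0472), IRF4 (0.0351) and PRDM1 (0.26).

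Leaving out 1 library with alisertib gave CDKN1A (-0.21 to 0.16) and CIITA (-0.0093 to 0.51). With SGC-CBP30 these ranges were LDHA (-0.52 to 2.19), JCHAIN (-2.30 to 1.02), IRF4 (-0.71 to 1.83), BIRC3 (-2.01 to 0.58), CD83 (-0.66 to 0.62), PSAT1 (-0.65 to 1.49), MYC (-0.29 to 1.499), EP300 (-0.0210 to 3.20), AURKA (-0.22 to 1.66), AURKB (-0.0809 to 0.12), CCNB1 (-0.0395 to 1.41), BCL6 (-0.23 to 2.62) and MCL1 (-0.23 to 1.60). With the combination these ranges were LDHA (-0.63 to 2.08), UTP20 (-0.82 to 2.82), JCHAIN (-2.56 to 0.76), BIRC3 (-1.72 to 0.87), CD83 (-0.64 to 0.64), PSAT1 (-0.71 to 1.43), MYC (-0.51 to 1.28), AURKB (-0.0248 to 0.18), BCL6 (-0.16 to 2.69), BCL2 (-0.0636 to 1.89), MCL1 (-0.13 to 1.69) and IRF4 (-0.66 to 1.87). For the combination against SGC-CBP30 these ranges were CDKN1A (-0.0804 to 0.32), BCL6 (-0.11 to 0.26), CIITA (-0.0721 to 0.0693), BCL2 (-0.35 to 0.13), MCL1 (-0.0630 to 0.25) and IRF4 (-0.0169 to 0.11). For the interaction these ranges were CREBBP (-2.14 to 0.11), CDKN1A (-0.0559 to 0.34), CIITA (-0.52 to 0.0079) and PRDM1 (-1.31 to 0.0146).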

Other observations

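The values in the following paragraphs were chosen for mention after the data had been seen, while the gene lists themselves were fixed before.

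Several genes that the report does not cover passed. MXD4, a MAX partner that opposes MYC, rose against alisertib in both fits (1.28 ± 0.12 with all 8 libraries, adjusted p = 0.0095), from 90 and 83 to 198 and 226. In the 7-library fit only, TXNIP rose with the combination (1.67 ± 0.31, adjusted p = 0.0291), and so did ZCCHC24 (1.93 ± 0.25, adjusted p = 0.0136), both of the BET bromodomain list. In that fit BIRC3, an NF-kB target, fell with SGC-CBP30 (-2.01 ± 0.21, adjusted p = 0.00996), as did CXCR5 (-1.39 ± 0.15, adjusted p = 0.0107).

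Other lists passed camera in some comparisons. None passed with an estimated correlation, a test with only 4 or 3 residual degrees of freedom. Ribosomal proteins were lower than other genes with alisertib (adjusted p = 0.000585 and 7.54e-05 in the 8- and 7-library fits, adjusted p = 0.814 and 0.671 with an estimated correlation), with medians of 0.05 and -0.03. The 8-library median of ribosomal proteins became -0.91 after centring and 0.29 after quantile normalization, and the 7-library one 0.05 after quantile normalization. Ribosomal proteins were also lower for the combination against SGC-CBP30 (0.000259 and 9.32e-08, adjusted p = 0.775 and 0.415 with an estimated correlation), with a median of -0.06 in each fit. Glycolysis and hypoxia genes were lower with alisertib (0.00218 and 0.00776, adjusted p = 0.814 and 0.496 with an estimated correlation), with an 8-library median of -0.03 and mean of 0.27. ATF4 and unfolded-protein stress genes were lower with SGC-CBP30 (4.92e-05 and 8.52e-06, adjusted p = 0.461 and 0.0587 with an estimated correlation), with a median of 0.03 and a mean of -0.02 in the 8-library fit and -0.44 in the 7-library fit, where 3 of 22 fell (14 adjusted over the list alone). For the combination against SGC-CBP30 these stress genes were higher (0.0391 and 0.0295, adjusted p = 0.912 and 0.361 with an estimated correlation). BET bromodomain genes were lower with SGC-CBP30 (0.0329, adjusted p = 0.355 with an estimated correlation) and the combination (0.0106, adjusted p = 0.315 with an estimated correlation) in the 8-library fit, with medians of -0.13 and -0.16 but means of 0.11 and 0.15. In the 7-library fit the BET bromodomain medians were 0.15 (adjusted p = 0.721, higher) and 0.08 (adjusted p = 0.958), and against alisertib 0.44 (adjusted p = 0.195), where 6 members rose and 3 fell. MYC targets were lower with alisertib in the 7-library fit (0.0218, adjusted p = 0.69 with an estimated correlation), with a median of 0.02. Histone genes were lower with the combination in the 8-library fit (3.81e-08, adjusted p = 0.432 with an estimated correlation, median -1.03). Their 7-library median was 0.11. In the 8-library fit interferon response genes were lower with the combination (0.00353, adjusted p = 0.432 with an estimated correlation, median 0.09). They were lower against alisertib too (0.0226, adjusted p = 0.694 with an estimated correlation). Against SGC-CBP30 they were lower as well (0.000259, adjusted p = 0.775 with an estimated correlation). Sterol biosynthesis genes were lower there too (0.00807 and 1.36e-05, adjusted p = 0.912 and 0.291 with an estimated correlation). Immediate-early and heat-shock genes were higher there with all 8 libraries (0.00807, adjusted p = 0.912 with an estimated correlation). Mitochondrial genome genes were higher in the 7-library fit with alisertib (0.00776, adjusted p = 0.69 with an estimated correlation, median 0.67) and with SGC-CBP30 (0.0357, adjusted p = 0.825 with an estimated correlation, median 0.36). MHC class I genes were lower in that fit with SGC-CBP30 (median -0.30) and the combination (median -0.22), on only 6 tested members. Of the 16 listed, 9 were at 0 in all 8 libraries. Oxidative phosphorylation genes were lower against SGC-CBP30 in the 7-library fit (median -0.0088).

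Besides markers of other cell types, 4 lists passed in no comparison of either fit. The smallest camera adjusted p was 0.538 and 0.0566 for E2F and S-phase genes, 0.584 and 0.33 for p53 targets, 0.584 and 0.153 for apoptosis regulators, and 0.144 and 0.129 for acetyltransferase, bromodomain and Aurora genes in the 8- and 7-library fits. Most markers of other cell types were listed at 0, which may be failed estimates and does not show their absence (of the T and NK cell markers 10 of 16, of the myeloid markers 9 of 12). The 14 stromal and epithelial markers were listed at 0 in all libraries. No myeloid marker exceeded 3, and their 3 tested members did not pass (smallest adjusted p = 0.307). No T and NK cell marker exceeded 3 either. In the 8-library fit camera placed their list of 5 tested members lower than other genes with SGC-CBP30 (adjusted p = 0.000353, 0.319 with an estimated correlation). The same held with the combination (0.000614, 0.315 with an estimated correlation). Below 0 lay 4 of the 5 with SGC-CBP30 and 3 with the combination, and 1 fell past the threshold in each. Fry also passed this list in that fit for SGC-CBP30, the combination and the combination against alisertib (adjusted p = 0.0219, 0.0306 and 0.035).

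A stretch of chromosome 6 from HLA-F to HLA-DPB1 (29722775 to 33087201, GRCh38) held many genes listed at 0. There, 105 of 127 coding genes (82.7%) were at 0 in all 8 libraries, against 6877 of 18843 (36.5%) in the rest of the genome. TUBB, a tubulin gene that dividing cells use, was listed at 1 or 2 in every library.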
